A study of Homo sapiens with 2 samples.

How the data were processed

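The data were mRNA-seq libraries from a pancreatic cancer patient-derived xenograft, that is, a human tumour kept alive by growing it in mice. There were 2 libraries. The vehicle library came from a tumour of an animal given 0.9% saline, and the treated library from a tumour of an animal given gemcitabine at 100 mg/kg together with nab-paclitaxel at 30 mg/kg. Per the labels' protocols, RNA was extracted with QIAzol and libraries were made with the TruSeq RNA Library Prep Kit v2, which does not keep the strand of the RNA. Each group had 1 library, so no replicate error could be measured.

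The authors deposited a table of normalized signal per gene, with 1 column per library, in which read counts had been divided by a size factor. Per the submitters' processing notes, the tools included STAR 2.6.0c (an aligner), HTSeq 0.11.1 (a read counter) and DESeq2 (version not given), and the genome build was hg38. The gene annotation, the counting settings, any filter on genes and the way in which reads from the mouse host were handled are not given in the sources used here. Low values in each column were whole multiples of a fixed step, 1.16 in the vehicle column and 0.860 in the treated column, and 100% of the values in both columns came out as whole reads within a tolerance of 0.01. Reads were therefore recovered by dividing each column by its step. The product of the 2 steps was 1.00, a property of size factors that were estimated from these 2 libraries alone.

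The table had 26485 rows. In it, 28 rows carried calendar dates in place of gene symbols, an effect of spreadsheet software on names such as those of the septin genes, and they were left out because dates cannot be turned back into genes with certainty. They held 0.164% of the reads of the vehicle library and 0.160% of those of the treated library. Another 138 rows were left out because the tumour came from a patient: genes of the Y chromosome and of X inactivation, HLA genes, and genes with common whole-gene deletions. This left 26319 genes. Mitochondrially encoded genes had no rows under any of the names tried. Recovered totals were 7721621 reads in the vehicle library and 8819173 in the treated library, counted without the date-named rows.

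The measure of difference was log2((treated + 1)/(vehicle + 1)) of the deposited values, called the log2 ratio below. A pseudocount of 1 understates the ratios of genes with low values. Genes counted as measured had a mean of at least 20 over both libraries. Genes were counted as higher or lower at 2-fold, and members of gene lists at 1.5-fold. Every ratio has an exact conditional (Clopper-Pearson) 95% interval computed from the recovered reads. It covers counting error only, and neither the difference between animals nor that between library preparations is in it. The reads carry no molecular identifiers, so repeated copies of a molecule made during amplification are counted as if they were independent. The floor of 3 reads corresponded to 3.49 normalized counts in the vehicle library and 2.58 in the treated library. With 1 library per group, a quasi-likelihood count model in edgeR could not be fitted, because it leaves no residual degrees of freedom. No p-value is therefore given, and the differences are between these 2 libraries.

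Gene lists numbered 31 and were fixed before the data were examined. They covered calcium entry and handling, drug response, proliferation, stress, metabolism, chromatin, pancreatic cancer subtypes, other cell types and library quality. Another 6 lists (hepatocyte markers, IL-6 and acute phase genes, complement, antigen presentation outside the HLA genes, intestinal epithelium and replication-dependent histones) were written after a first look at the values and are reported only among the additional observations. For each list with at least 5 measured members, the median log2 ratio was given with a 95% interval of the median from order statistics, and with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. A further percentile was matched on both mean and transcript length, in 10 bins of each. Percentiles describe these 2 libraries and are not tests of the treatment. Members of a list are not independent of each other, so the interval of a median is a description as well.

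Named genes followed a rule set before the data were examined. It took the 12 highest and 12 lowest log2 ratios among genes with a mean of at least 100, the 2 highest and 2 lowest measured members of each list (all members of a list with fewer than 5 measured), and STIM1, STIM2, ORAI1, ORAI2, ORAI3, NFATC1, DDIT3, CDKN1A and MKI67. Some genes that the rule takes are not reported here. Genes named outside this rule are said to have been chosen after their values were seen. Coordinates, transcript lengths and GC content came from GENCODE 29 on GRCh38, the assembly that hg38 denotes, and 98.3% of the measured genes could be matched to a transcript. Length and GC content were those of a gene's longest protein-coding transcript, or else of its longest transcript. That transcript need not be the one the tumour expressed.

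Alternatives set before the data were examined were other pseudocounts, other filters on low values, scaling to library totals with or without ribosomal protein genes, scaling by edgeR's TMM method, a stricter call by counting interval, and sums in place of medians. Removal of the trend of the log2 ratio on transcript length or GC content (a lowess curve with a span of 0.3, fitted without the list in question) was added after the data had been seen, and so were the medians of the acute phase and complement lists without the genes among the 12 highest, and that of the intestinal list without the gene among the 12 lowest. The recovery of reads, the 2-fold calls, the counting intervals and the percentiles matched on mean expression were tested on simulated libraries with the depths of the real ones. Removal of a trend was tested on a planted trend with length. The alternative scalings and the percentiles matched on length were not tested on simulated data. In the simulation of 13101 genes, 99% of the genes changed 4-fold and 99% of those changed 2.83-fold were called at 2-fold, while counting error alone put 10 unchanged genes at 2-fold higher and 5 at 2-fold lower. The counting intervals covered the true ratio for 95.5% of genes, the intervals of list medians covered the true median in 96.9% of simulated lists, and 6 of 100 unchanged lists had a percentile outside 2.5 to 97.5. Simulated reads varied by counting error only, as the counting intervals assume, and simulated lists were random genes. These shares check the calculations and say nothing about variation between animals or about lists of related genes.

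Several genes cannot be read without care. Near-identical copies can trade reads with each other, which concerns PRSS1 and PRSS2, the SAA genes, tubulins, keratins, the paired SNORA73 genes and ribosomal protein genes with their pseudogenes. Of 148 named genes with coordinates, 7 had at least 20% of their exon bases under exons of another gene in the table, namely SNORA73A, RNU2-2P, CCNE2, ANKRD37, DDIT3, TP53BP1 and ERCC1, and their values are uncertain. For SNORA73A and RNU2-2P the other gene lies on the same strand, so the strand would not separate them. For the rest it lies on the opposite strand, and reads there cannot be assigned without the strand.

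Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and in R 4.3.3 with edgeR 4.0.16.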

Results

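Gene expression was compared between a vehicle-treated and a gemcitabine plus nab-paclitaxel-treated tumour of a pancreatic cancer patient-derived xenograft. Gemcitabine is a nucleoside analogue that blocks DNA synthesis, and nab-paclitaxel is an albumin-bound taxane that stabilises microtubules. The series concerns STIM1, the endoplasmic reticulum calcium sensor, and calcium-dependent epigenetic change in pancreatic cancer, so the comparison asks how the transcriptome of the tumour, STIM1 included, differed under chemotherapy. The vehicle library held 7721621 reads over 18243 genes with reads, and the treated library held 8819173 reads over 19349. The 10 most abundant genes took 6.06% of the reads of the vehicle library and 4.05% of those of the treated library. Each group had 1 library and no difference below has a replicate check. Intervals cover counting error only.

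The fibrinogen genes were among the largest positive differences, and small structural RNAs such as RN7SK among the largest negative ones. Of 13091 measured genes, 1126 (8.60%) were at least 2-fold higher in the treated library and 735 (5.61%) were at least 2-fold lower. Counting intervals excluded equality for all 1126 and all 735. The 2-fold threshold and the filter on the mean already bring this about, so it is no further support. At 4-fold, 246 genes were higher and 76 lower. Across the measured genes, Pearson's r of the log2 values of both libraries was 0.917, where genes are not independent replicates. The balance of the calls depended on the scaling and on the expression filter. Under the deposited scaling 60.5% of the calls were higher in the treated library. With a minimum mean of 100 the balance turned, with 424 genes higher and 527 lower, or 44.6% higher. Scaled to library totals, 1687 genes were higher and 358 lower, so that 82.5% were higher, and the median log2 ratio of all genes moved by 0.24. Totals taken without ribosomal protein genes gave 1604 higher and 390 lower, or 80.4% higher, with a shift of 0.21. After removal of the trend with transcript length, 1179 genes were higher and 473 lower.

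**Figure D1:**
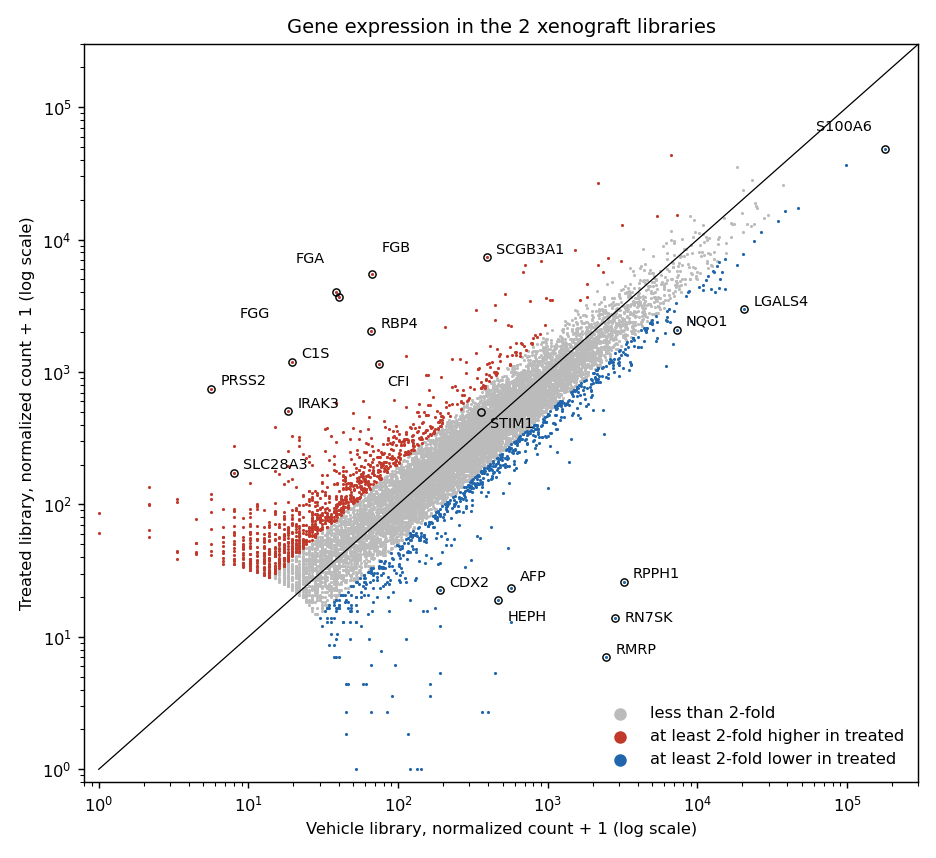
Normalized counts of each measured gene in the vehicle library (x axis, plus 1, log scale) and the treated library (y axis, plus 1, log scale), where each point is 1 gene and the line marks equal values. Red points are the 1126 genes at least 2-fold higher in the treated library and blue points the 735 at least 2-fold lower, and circles mark genes named in the text.

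Among genes with a mean of at least 100, the 12 highest log2 ratios included several genes of secreted proteins. The 3 chains of fibrinogen, the clotting protein that also rises in the acute phase response, stood together: FGA was 37.2 normalized counts in the vehicle library and 4046 in the treated library (log2 ratio 6.73, 95% counting interval 6.27 to 7.31), FGB was 66.3 and 5512 (6.36), and FGG was 39.5 and 3699 (6.51). These genes are neighbours on chromosome 4 (FGA at 154583126 to 154590766, GRCh38). The complement protease C1S was 18.6 and 1197 (5.93, interval 5.30 to 6.82), and complement factor I (CFI) was 73.2 and 1146 (3.95). The retinol carrier RBP4 was 65.1 and 2023 (4.94), the paraoxonase PON1 was 6.97 and 274 (5.11), and the acute phase gene SAA2 was 18.6 and 329 (4.08). Also in this group were SCGB3A1, a secretoglobin of airway and other epithelia, at 394 and 7350 (4.22), OLFM4, a marker of intestinal crypts, at 13.9 and 380 (4.67), and IRAK3, an inhibitor of Toll-like receptor signalling, at 17.4 and 504 (4.78). Trypsinogen 2 (PRSS2) had the highest value, 4.65 and 748 (7.05, interval 5.97 to 9.21), on only 4 reads in the vehicle library.

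At the other end stood noncoding RNAs of 141 to 333 nucleotides. Shorter messages were lower as well, with a median of −0.53 for protein-coding genes with transcripts under 1000 nt and of −1.04 for ribosomal protein genes. RN7SK, which holds the elongation factor P-TEFb inactive, was 2824 normalized counts in the vehicle library and 12.9 in the treated library (log2 ratio −7.67, interval −8.61 to −7.05). The RNA of RNase MRP (RMRP) was 2467 and 6.02 (−8.46), and that of RNase P (RPPH1) was 3235 and 24.9 (−6.96). The spliceosomal RNAs RNU4-2 and RNU2-2P rested on 2 reads each in the treated library, with log2 ratios of −7.20 (interval −10.91 to −5.99) and −7.06 (−10.77 to −5.85). The small nucleolar RNAs SNORA73A (−6.39) and SNORA73B (−5.45) and the signal recognition particle RNA RN7SL2 (−3.55) completed this group. The 35 measured genes of small structured RNAs, RMRP not among them, held 0.118% of vehicle reads and 0.0101% of treated reads. How much of such RNAs each mRNA-seq preparation kept is not known, so these values need not follow their levels in the tumours. A difference in RNA quality or library preparation was not tested. The 4 protein-coding genes among the 12 lowest were the iron oxidase HEPH, at 467 and 18.1 (−4.62), alpha-fetoprotein (AFP), at 565 and 22.4 (−4.60), the adenylate kinase AK5, at 191 and 11.2 (−3.98), and CDX2, the intestinal homeobox factor, at 191 and 21.5 (−3.09).

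STIM1 (chromosome 11, 3854527 to 4093210, plus strand) was 358 normalized counts in the vehicle library and 501 in the treated library, from 308 and 582 reads. This is a log2 ratio of 0.48 (interval 0.28 to 0.69) or 1.40-fold, short of the 2-fold and 1.5-fold thresholds under the deposited scaling. Scaled to library totals it was 0.72, which is past 1.5-fold. STIM2, the other sensor, had a log2 ratio of 0.18 (−0.10 to 0.45). Among the channel subunits that STIM proteins open, ORAI2 was at 0.29 (0.14 to 0.45), ORAI3 at 0.29 (0.02 to 0.57) and ORAI1 at −0.25 (−0.56 to 0.06), whose interval includes no difference. Of 11 measured genes of store-operated calcium entry, 2 were at least 1.5-fold higher, none was lower and 9 lay between, with a median of 0.29 (interval of the median 0.0491 to 0.59) at percentile 91.0 of random lists. The channel regulator CRACR2A had the highest value (1.58, interval 0.93 to 2.36), TRPC1 was at 0.59 (−0.32 to 1.61) and SARAF, a negative regulator of the channel, at 0.05 (−0.03 to 0.13).

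In the list of calcineurin and NFAT genes, which act downstream of calcium entry, some members were higher and none was 1.5-fold lower. The transcription factor gene NFATC4 was 388 and 878 (log2 ratio 1.18, from 334 and 1021 reads) and the calcineurin regulator RCAN2 was 22.1 and 80.0 (1.81, 1.13 to 2.65), whereas NFATC2 was at −0.53 (−0.95 to −0.12), PPP3CB, a catalytic subunit of calcineurin, at −0.43 and NFATC1 at 0.12 (−0.38 to 0.62). In all, 4 of 13 measured members were higher, none lower and 9 between (median 0.06, percentile 67.5). Calcium pumps, release channels and buffers went both ways, with 4 of 23 higher, 5 lower and 14 between (median −0.19, percentile 48.5). The reticulum calcium pump ATP2A3 (1.58) and the Golgi pump ATP2C2 (1.24) were the highest, and the receptor channel ITPR2 (−0.79) and the calcium-binding protein S100A6 the lowest. S100A6 was the most abundant gene of the vehicle library, at 178640, and was 48080 in the treated library (−1.89). The ratio of the summed values of this list, of which S100A6 is the largest part, was −1.35.

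**Figure D2:**
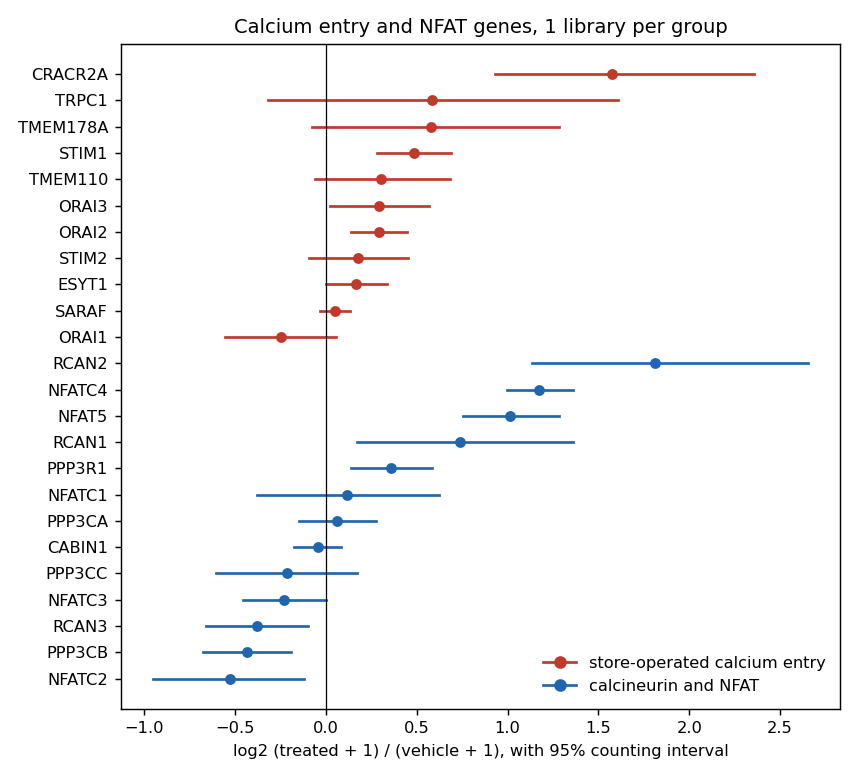
Log2 ratios (x axis, treated over vehicle with a pseudocount of 1) of the measured genes of store-operated calcium entry (red) and of calcineurin and NFAT (blue), 1 library per group. Points are genes and bars are 95% counting intervals, and STIM1 lies at 0.48 while CRACR2A and RCAN2 lie at 1.58 and 1.81.

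Histone and chromatin modifiers, the class of genes nearest to the epigenetic question of the series, were slightly higher as a group. Of 29 measured, 7 were at least 1.5-fold higher, none was lower and 22 lay between, with a median of 0.34 (interval of the median 0.11 to 0.49) at percentile 99.98 (97.6 when random lists were also matched on transcript length). The histone H3K27 demethylase KDM6B was 141 and 324 (1.20, interval 0.91 to 1.51) and the deacetylase HDAC9 was at 0.93, while the deacetylases HDAC1 and HDAC2 were at −0.58 and −0.54. The log2 ratio of all measured genes was greater for longer transcripts, and the median of this list was 0.19 once that trend was removed.

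That trend ran through the whole comparison. For protein-coding genes with transcripts under 1000 nt the median log2 ratio was −0.53 (453 genes), from 1000 to below 2000 nt it was −0.38 (2117 genes), from 2000 to below 4000 nt −0.11 (4809 genes), from 4000 to below 8000 nt 0.13 (3923 genes), and for 8000 nt or more 0.21 (1032 genes). Spearman's rho across genes was 0.315 for length, 0.039 for GC content and −0.267 for mean expression.

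**Figure D3:**
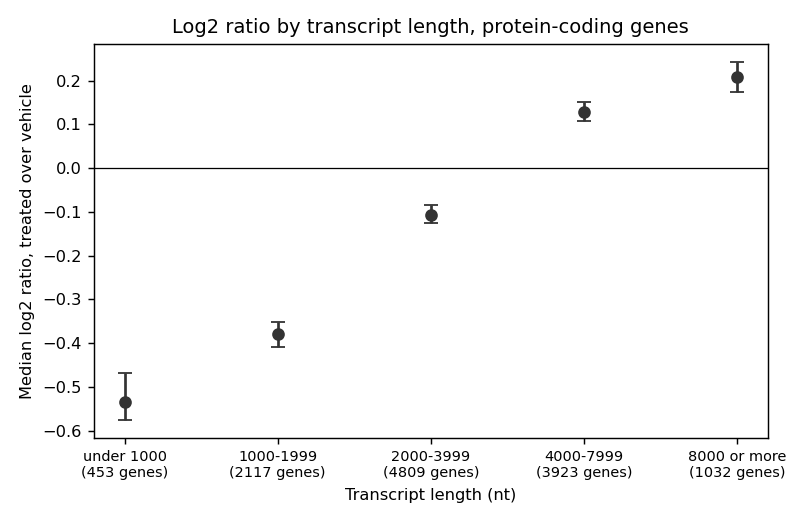
Median log2 ratio (y axis, treated over vehicle) of measured protein-coding genes in 5 classes of transcript length (x axis, nt), with bars for the 95% interval of each median. The medians run from −0.53 in the shortest class to 0.21 in the longest.

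DNA replication and mitosis genes had medians below 0, although most of their members differed by less than 1.5-fold. Of 27 DNA replication genes, 10 were at least 1.5-fold lower, 1 was higher and 16 lay between (median −0.40, interval −0.66 to −0.28, percentile 1.14). The replicative helicase components GINS2 and CDC45 were at −1.29 and −1.21, whereas GINS3 was at 0.59 and CCNE2 at 0.28 (−0.44 to 1.05). Mitotic genes had 7 of 26 lower, none higher and 19 between (median −0.37, interval −0.56 to −0.19, percentile 1.46). The mitotic kinase CDK1 was 790 and 385 (−1.04, interval −1.21 to −0.87) and DLGAP5 was at −1.03, while BUB1B (0.14, −0.13 to 0.42) and HMMR (0.18, −0.31 to 0.69) did not differ beyond counting error. The proliferation marker MKI67 was at −0.14 (−0.25 to −0.04), and at 0.10 when scaled to library totals. DNA damage repair genes had 4 of 25 lower, 1 higher and 20 between (median −0.36, interval −0.50 to 0.00656, percentile 2.21), with ERCC1 (−1.42, a gene whose exons partly overlap another gene) and RAD51C (−0.93) lowest and TP53BP1 (0.62) and BRCA2 (0.58, −0.12 to 1.35) highest. Scaled to library totals, the medians of the replication and mitosis lists were −0.16 and −0.13. After removal of the length trend, described above, the median was −0.34 (−0.63 to −0.20) for replication, −0.35 (−0.55 to 0.0495) for mitosis and −0.19 (−0.52 to 0.00754) for repair, so that the intervals of the latter lists included 0.

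Gemcitabine enters cells through nucleoside transporters and is activated by kinases and inactivated by deaminases. In the list of its uptake and metabolism, 8 of 18 measured genes were lower, 3 higher and 7 between (median −0.50, interval −0.73 to −0.09), at percentile 0.870, or 3.10 when length was matched too. After removal of the length trend the median was −0.32 and its interval, −0.52 to 0.18, included 0. The exceptions were large. The concentrative transporter SLC28A3 was 6.97 and 172 (4.44, interval 3.48 to 6.09), and cytidine deaminase (CDA), the enzyme that inactivates gemcitabine, was 269 and 734 (1.45, 1.24 to 1.67). The nucleotidases NT5C (−1.16) and NT5C3A (−0.91) were the lowest members. For the taxane, tubulins and microtubule regulators had 2 of 17 higher, 5 lower and 10 between (median −0.02, percentile 82.3), with MAP1B at 1.13, TUBB2B at 0.66 (−0.18 to 1.61), TUBB4B at −0.86 and TUBA1C at −0.88. Drug efflux transporters and taxane metabolism had 3 of 10 higher, 2 lower and 5 between (median 0.10, percentile 81.8). In that list the taxane-oxidising enzyme CYP2C8 was at 1.36, the efflux pump gene ABCB1 was 16.3 and 31.0 (0.89, 0.00 to 1.93), MVP was at −0.64 and ABCC4 at −1.26.

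Genes of damage and death responses went in both directions. Of 25 p53 targets, 7 were higher, 3 lower and 15 between (median 0.15, percentile 87.0). The stress cytokine GDF15 was 41.8 and 189 (2.15, interval 1.66 to 2.73), TP53INP1 was at 1.03 and the cell cycle inhibitor CDKN1A at 0.60 (0.35 to 0.87), against −0.75 for TP53I3 and −0.80 for CCNG1. Apoptosis genes had 4 of 21 higher, 3 lower and 14 between (median 0.15, percentile 94.3), with the proapoptotic BMF at 53.5 and 312 (2.52), APAF1 at 1.31, the inhibitor XIAP at −0.76 and the death ligand TNFSF10 at −1.05. Endoplasmic reticulum stress genes had 3 of 27 higher, 5 lower and 19 between (median −0.11, percentile 69.2). In that list CHAC1, which degrades glutathione, was 9.30 and 85.2 (3.06, 2.16 to 4.45) and the stress sensor ERN1 was at 0.66, but DDIT3 was at 0.16 (−0.06 to 0.38), TRIB3 at −0.78 and SDF2L1 at −0.96. AP-1 and immediate early genes had 7 of 21 higher, 5 lower and 9 between (median 0.09, percentile 91.3), from DUSP1 (1.35) and FOSB (1.20) to KLF6 (−0.74) and IER3 (−0.75).

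Cholesterol synthesis genes were lower almost throughout. Of 19 measured genes, 17 were at least 1.5-fold lower, none was higher and 2 lay between. The median was −1.08 (interval −1.43 to −0.76), below each of the 10000 random lists, and −1.03 after the length trend was removed. The isomerase IDI1 was 1444 and 477 (−1.60, interval −1.75 to −1.45) and the demethylase CYP51A1 was 871 and 292 (−1.57), while HMGCS1 was at −0.49. Oxidative stress response genes had 9 of 17 lower, 2 higher and 6 between (median −0.63, percentile 0.310). The interval of this median, −1.11 to 0.0158, included 0, as did that after removal of the length trend (−0.35, −0.98 to 0.00494). Among them the quinone reductase NQO1 was 7267 and 2090 (−1.80) and thioredoxin (TXN) was 3194 and 1068 (−1.58), against 0.85 for OSGIN1 and 0.65 for the metallothionein MT2A. Hypoxia and glycolysis genes had 8 of 21 lower, 2 higher and 11 between (median −0.02, percentile 89.5), with ANKRD37 (−1.12) and ANGPTL4 (−1.03) lowest and HK2 (0.71) and BNIP3 (1.74) highest.

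Many genes of the classical subtype of pancreatic cancer were lower, although not all. Classical subtype genes, which mark the more differentiated form of pancreatic cancer, had 11 of 21 lower, 4 higher and 6 between (median −0.69, interval −1.26 to −0.01, percentile 0.050). The galectin LGALS4 was 20519 and 2983 (−2.78, interval −2.84 to −2.73) and CLRN3 was 334 and 56.8 (−2.53), but the trefoil peptide TFF3 was 444 and 2457 (2.47) and cathepsin E (CTSE) was 343 and 1055 (1.62). The length trend bore on this list, whose median was −0.23 (−1.12 to 0.26) after its removal. Basal-like subtype genes showed no common direction, with 5 of 17 higher, 4 lower and 8 between (median −0.02, percentile 65.4). In that list VGLL1 was at 1.64, LEMD1 at −0.80 and AREG at −0.86. Epithelial junction and keratin genes had 2 of 21 higher, 4 lower and 15 between (median −0.05, percentile 94.3), although their most abundant member, keratin 19 (KRT19), was 98445 and 36758 (−1.42) and KRT8 was at −1.23. OVOL1 (1.15) and TJP1 (0.70) were the highest of them.

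Mucin genes were higher almost throughout. Of 12 measured, 10 were at least 1.5-fold higher, 1 was lower and 1 lay between, with a median of 1.09 (interval 0.60 to 2.14) above each of the 10000 random lists. The gastric mucin MUC6 was 704 and 6453 (3.19, interval 3.08 to 3.32), MUC21 was 2.32 and 109 on 2 vehicle reads (5.05, 3.67 to 8.62), MUC12 was at 0.55 (−0.26 to 1.44) and MUC17 at −0.88 (−1.75 to −0.09).

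Many mesenchymal genes were higher, as were some inflammatory genes and most measured markers of fibroblasts, endothelial cells and immune cells. Of 20 mesenchymal transition genes, 12 were higher, none lower by 1.5-fold and 8 between (median 0.79, interval 0.05 to 1.23, above each random list). The median was 0.32 with a minimum mean of 100, and the ratio of summed values was 0.26. The metalloproteinases MMP9 (22.1 and 114, 2.32) and MMP2 (284 and 1192, 2.07) led this list, while ITGB6 was at −0.50 and PLAUR at −0.56. NF-kB targets and inflammatory cytokines had 7 of 22 higher, 1 lower and 14 between (median 0.30, percentile 99.6), and the interval of this median, −0.04 to 0.62, included 0. It excluded 0 after removal of the length trend (0.56, 0.11 to 0.83). After removal of the GC trend it did so narrowly (0.37, 0.0137 to 0.69). Removal of a trend also takes away the level of all measured genes, whose median log2 ratio was −0.06. The GC trend was almost flat, so the latter value says nothing about GC content. IL6 was 5.81 and 50.8 (2.93, interval 1.82 to 4.80), the chemokine CXCL6 was 544 and 2255 (2.05), IL1RN was at −0.26 (−0.56 to 0.03) and IL18 at −1.55. Interferon response genes differed little, with 2 of 29 higher, none lower and 27 between (median 0.05, percentile 92.4), from MX2 (0.92) and XAF1 (0.63) to IFI27 (−0.54) and IFIT1 (−0.55).

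Fibroblast markers, measured beside these groups, had 14 of 20 higher, none lower by 1.5-fold and 6 between (median 0.86, interval 0.56 to 1.12). The matrix proteoglycans biglycan (BGN, 259 and 1246, 2.26) and decorin (DCN, 81.4 and 386, 2.23) were the highest, and FAP (0.21, −0.13 to 0.56) and COL6A3 (−0.53) the lowest. Endothelial markers had 8 of 11 higher, none lower and 3 between (median 0.96, interval 0.45 to 1.69), led by TEK (2.12) and PECAM1 (459 and 1485, 1.69), with ERG at 0.45 (−0.45 to 1.45) and EGFL7 at 0.28 (−0.06 to 0.63). Of 23 immune cell markers only 13 were measured, with 10 higher, none lower and 3 between (median 1.07, interval 0.20 to 2.26). S100A8 was 2.32 and 103 (4.97, interval 3.59 to 8.53 on 2 vehicle reads) and the leukocyte gene PTPRC was 8.14 and 55.9 (2.64). Both passed the filter on the mean through the treated library alone. The macrophage genes AIF1 and CD68 were at −0.08 and −0.09. All 3 lists may hold reads from mouse cells, whose handling is not given. Percentiles were 100 for the fibroblast and immune lists and 99.7 for the endothelial list. No gene of these 3 lists is also in the mesenchymal list.

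Adipocyte and muscle markers had 3 of 6 higher, 2 lower and 1 between (median 0.67, −1.49 to 3.75, percentile 88.7), from PLIN4 (3.75, interval 2.31 to 7.32 on 2 vehicle reads) and ACTA1 (1.45) to TNNI2 (−0.89) and CIDEC (−1.49). In the list of acinar and endocrine markers only the trypsinogens were measured, PRSS1 (20.9 and 320, 3.87) and PRSS2. Of its unmeasured members, chosen after their values were seen, carboxypeptidase A1 (CPA1), chymotrypsinogen B1 (CTRB1) and pancreatic lipase (PNLIP) had no reads in either library, which allows up to 3.49 normalized counts in the vehicle library and 2.58 in the treated library. Without the genes of the other-cell-type lists, 1103 genes were at least 2-fold higher and 734 lower.

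Cytosolic ribosomal protein genes, taken as a group of short and abundant messages, were lower in the treated library. Of 37 measured, 35 were at least 1.5-fold lower, none was higher and 2 lay between (median −1.04, interval −1.13 to −0.92, below each random list). RPL13A was 12267 and 4222 (−1.54), while RPS15 was at −0.29 and RPLP1 at −0.20. The median was −0.80 when scaled to library totals and −0.68 after the length trend was removed. RPLP1 then lay at 0.0431 and 0.26, and RPS15 at 0.22 after the length trend was removed.

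**Figure D4:**
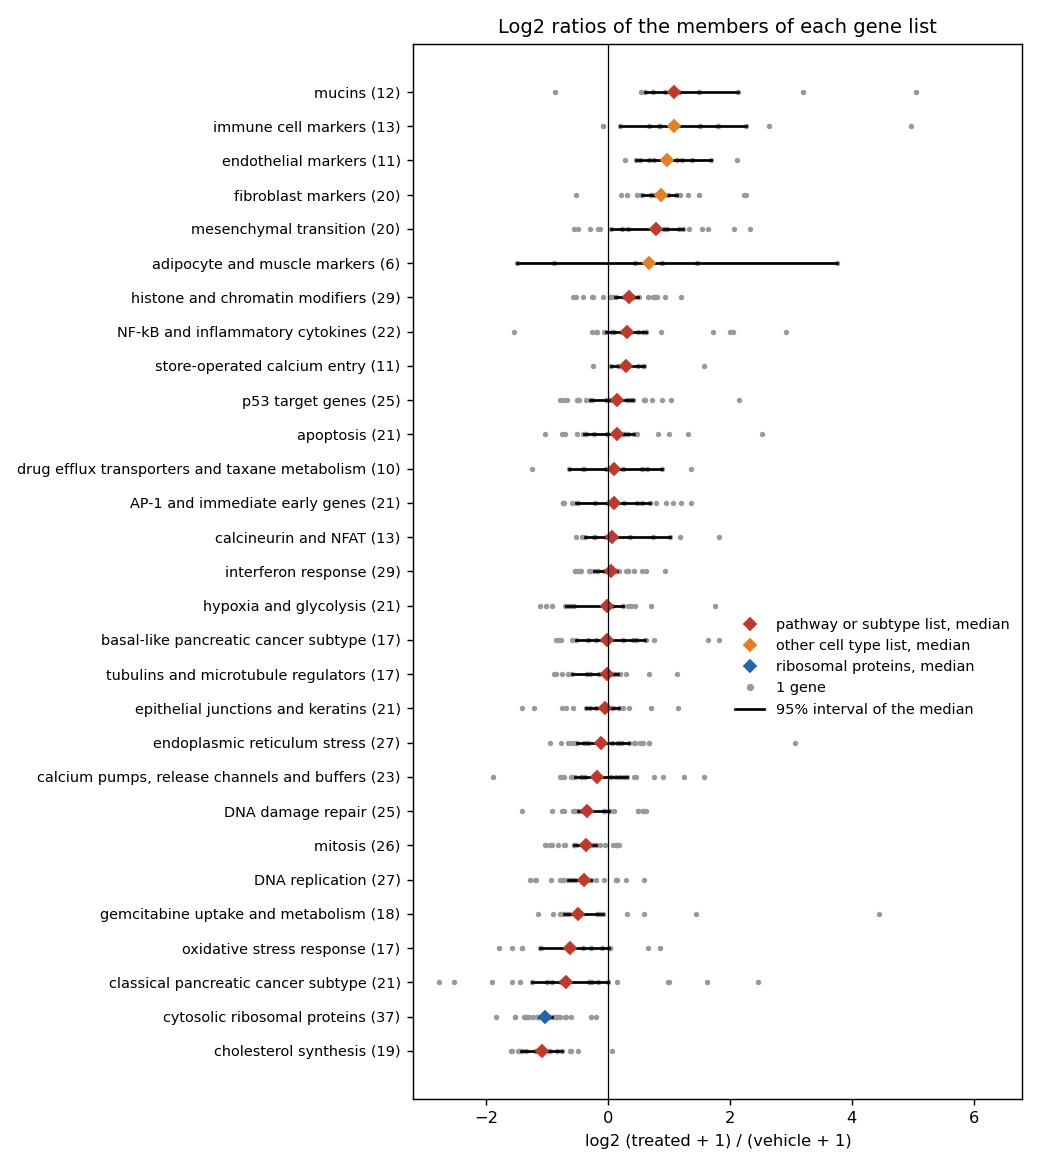
Log2 ratios (x axis, treated over vehicle with a pseudocount of 1) of the measured members of the 29 lists fixed before the data were examined that had a percentile, with the number of measured members in brackets. Grey points are genes, diamonds are list medians and bars are 95% intervals of the medians, which run from −1.08 for cholesterol synthesis to 1.09 for mucins.

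Across the 29 lists with a percentile, 7 medians lay above percentile 97.5 and 8 below 2.5, where random lists would give 1.45 outside these bounds. Of these 15, 14 also lay outside them when random lists were matched on transcript length. The 1.45 holds for lists of unrelated genes, whereas members of the fixed lists are not independent, so the excess does not measure an effect of treatment. Medians of lists given without an interval had one that included 0. Scaled to library totals, the median was 0.53 for store-operated calcium entry, −0.11 for DNA repair, −0.26 for gemcitabine uptake and metabolism, 0.54 for NF-kB targets, −0.39 for oxidative stress, 0.59 for chromatin modifiers and −0.45 for the classical subtype. The ratio of summed values was 0.17 for store-operated calcium entry, −1.08 for oxidative stress, 0.13 for chromatin modifiers, −1.33 for the classical subtype, 0.57 for immune markers and −0.33 for adipocyte and muscle markers, whose median was −0.89 with a minimum mean of 100.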

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

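Length-adjusted and GC-adjusted values were chosen after the data had been seen, and the other settings before. Of 20 recomputed counts of 2-fold genes, 12 stayed within 1.5 times the main count. Without a filter on low values 3349 genes were higher and 1923 lower, because more genes with few reads enter. With a minimum mean of 100 the number higher was 424 against 527 lower, so that fewer calls were higher than lower, and among genes whose counting interval lay wholly beyond 2-fold it was 492 against 343 lower, both stricter by construction. The number lower was 358 when scaled to library totals, 390 when scaled to totals without ribosomal protein genes, settings that shift the median log2 ratio of all genes by 0.24 and 0.21, and 473 after removal of the length trend. Of 235 recomputed list medians over 29 lists, 223 stayed within the interval of the main median and none whose interval excluded 0 changed sign. Some intervals were wide, so a median could change sign and still lie within. With a minimum mean of 100, the adipocyte and muscle median went from 0.67 to −0.89 and the apoptosis median from 0.15 to −0.13. Scaled to library totals, the medians were −0.16 for DNA replication, −0.13 for mitosis, 0.22 for tubulins, 0.29 for the interferon response, 0.59 for chromatin modifiers, 0.19 for epithelial junctions and keratins and −0.80 for ribosomal proteins, and STIM1 was at 0.72. Summed values, in which abundant members count most, gave −1.35 for calcium pumps and buffers, −0.23 for the interferon response, −1.33 for the classical subtype and −0.90 for epithelial genes. Ribosomal proteins were at −0.68 after removal of the length trend. Among 148 named genes, 481 of 592 recomputed values stayed within their counting interval, 107 left it, and 4 whose interval excluded 0 changed sign: MKI67 (0.10) and RPLP1 (0.0431) when scaled to library totals, and RPLP1 (0.26) and RPS15 (0.22) after removal of the length trend. What lies behind the length trend was not tested. Depth limits genes near 20 normalized counts, where 3 reads amount to 3.49 or 2.58. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out.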

Other observations

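The lists in this part, the genes named in it beyond the fixed rule, and the tests of library-total scaling and of the liver messages other than ALB were chosen after the results had been seen, whereas the other tests were written before the values they measure were computed.

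Acute phase and complement genes were drawn into lists because some of them stood among the 12 highest genes, so the lists are not independent of those. Of 21 measured IL-6 and acute phase genes, 15 were at least 1.5-fold higher, none lower and 6 between (median log2 ratio 2.18, interval 0.46 to 5.51, above each of 10000 random lists). Without FGA, FGB, FGG and SAA2, 11 of 17 were higher, none lower and 6 between (median 1.41, interval 0.40 to 3.06). Serum amyloid SAA1 was 37.2 and 583 (3.94), ITIH4 was 227 and 1261 (2.47), the IL-6 feedback inhibitor SOCS3 was 133 and 354 (1.41), and C-reactive protein (CRP) was 1.16 and 98.9, on a single vehicle read (5.53, 3.90 to 11.73). The transcription factor STAT3 was at 0.46 and JUNB at −0.52. Of 15 complement genes, 11 were higher, 1 lower and 3 between (median 1.30, interval 0.50 to 3.53, above each random list): the central component C3 was 3132 and 12871 (2.04), C1R was 113 and 1314 (3.53), C4BPA was 20.9 and 307 (3.81) and CFB was 2327 and 5728 (1.30), while the membrane inhibitor CD59 was at −0.63. Without C1S and CFI, 9 of 13 complement genes were higher, 1 lower and 3 between (median 1.21, interval 0.20 to 2.70).

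Antigen presentation genes outside the HLA genes had 4 of 13 higher, 1 lower and 8 between (median 0.17, interval −0.13 to 1.04, percentile 96.1), but the MHC class II chaperone CD74 was 900 and 6924 (2.94, 2.84 to 3.05) and the class II transactivator CIITA was 10.5 and 60.2 (2.42, 1.52 to 3.71). Against these, the class I genes B2M (0.27) and TAP1 (0.17) differed little. Intestinal epithelium genes had 6 of 11 lower, 2 higher and 3 between. Their median of −1.10 lay below each random list, with an interval, −2.82 to 1.42, that included 0. The list, written after a first look at the values, leaves out OLFM4 (4.67), named above as a marker of intestinal crypts. Its place among random lists therefore depends on which genes were picked, and no common direction is drawn from it. Without CDX2, one of the 12 lowest genes and seen before this list was written, the median was −0.65 (−2.78 to 1.42). Together with CDX2 and LGALS4, the glucose transporter SLC5A1 was 2383 and 336 (−2.82) and HNF4G was 380 and 176 (−1.10), while the brush border enzyme ANPEP was 5347 and 14995 (1.49) and CDHR2 was at 1.42. Hepatocyte markers went both ways, with 2 of 6 higher, 2 lower and 2 between (median −0.25, interval −1.21 to 2.43, percentile 21.6), and albumin (ALB) was 15613 and 9418 (−0.73).

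Fibrinogen and acute phase genes are made mostly by the liver, so RNA from liver cells was weighed as a source. ALB divided by FGA in the treated library was 2.33 (upper bound 2.41), which meets the value written in advance for liver RNA, but that criterion was a poor one, since ALB was already abundant in the vehicle library and was lower, not higher, beside the fibrinogen genes. The abundant liver messages APOA1, APOA2, APOC3 and TTR together reached 9.46 normalized counts in the treated library, 0.00234 of FGA (upper bound 0.00419). This goes against RNA from human liver cells only. The tumour grew in mice, so liver cells of the host would be mouse cells. On these the values cannot decide, because the handling of mouse reads is not given, so liver cells as a source stay open. The trend with length is not the whole cause either, since the median of the acute phase list was 2.46 (0.58 to 5.79) after its removal. No biological explanation was tested, and treatment, animal and tumour piece are confounded with 1 library per group.

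Fibroblast, endothelial and immune markers were higher together. Their length-adjusted median over 44 genes was 0.97 (0.66 to 1.28), so the length trend does not account for them. That trend spanned only 0.70 in log2 ratio over the bulk of measured genes. This is less than each list's unadjusted median, so its removal could hardly have given another result. The test set in advance assumed that a larger share of non-tumour cells, human or mouse, raises the 3 lists alike. Their length-adjusted medians of 0.85, 0.95 and 1.62 differed by 0.77, between the bounds set for and against this explanation. Each cell type could also change its share separately, so this spread cannot decide the question. A larger share of non-tumour cells therefore cannot be told apart from differences within these cells or in the tumour cells. Wide intervals and the unknown handling of mouse reads also keep it open. The same holds for the mesenchymal genes measured beside them, which fibroblasts also express.

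Ribosomal protein messages were lower almost as a block. Their median stayed at −0.68 (−0.84 to −0.55) after removal of the length trend and at −0.80 when scaled to library totals, over 37 genes, so neither is the whole cause, although length goes with part of it. The length trend spanned 0.68 over the bulk of measured genes, and scaling to library totals shifts ratios by 0.24. Both are smaller than the unadjusted median of −1.04, so neither could have removed it. Removal of the GC trend left −0.99, but that trend was almost flat across genes (Spearman's rho 0.039), so this decides nothing about GC content. No biological explanation was tested, and a difference in RNA quality or library preparation between the libraries was not tested and stays open.

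Small structured RNAs (snRNA, snoRNA, scaRNA and related genes) had 23 of 35 measured genes at least 2-fold lower and none higher, with a median of −3.35 (−5.45 to −0.96), the same with the 4 genes without treated reads set at 3 reads, and their sum was 10577 in the vehicle library and 770 in the treated library. The class was not uniform. The shortest of these RNAs, SNORD104 (70 nt), SNORD36A (73 nt) and SNORD35A (86 nt), were at −0.11, 0.15 and −0.96. The lowest ratios were thus not in the shortest of them. RMRP, the lowest of the named genes, is not among these 35 genes or in these sums. As for the ribosomal protein messages, a difference in RNA quality or library preparation was not tested and stays open for these RNAs. Replication-dependent histone genes had 5 of 15 lower by 1.5-fold, none higher and 10 between (median −0.32, interval −0.65 to −0.02, percentile 3.44, or 57.8 with length matched). Removal of the length trend turned the direction of this list, to a median of 0.19 (−0.16 to 0.48), so no direction is drawn from it.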
